A study of Mus musculus with 4 samples.

How the data were processed

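Testes of control and Dis3 conditional knockout mice at postnatal day 17 were sequenced, with 2 libraries per genotype. Per the labels' protocols, RNA was isolated from testes, cDNA was primed with random and poly(T) primers, and libraries were strand-selected and depleted of targeted transcripts before PCR. The labels also name the molecule as polyA RNA. Groups and replicate numbers were taken from the sample titles.

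The values used are raw read counts, per the file headers made by the authors with featureCounts 1.6.4. Genes were counted by exons on the strand of the gene with the GENCODE M18 annotation, per the file headers. Options that keep multi-mapping reads or reads overlapping several genes do not appear in the recorded commands, so such reads were left out, which lowers counts of near-identical genes. The same counter was run on regions of 3000 bases directly upstream of genes, on the same and on the opposite strand, per the file headers. The submitters' processing notes name cutadapt, HISAT2 and the genome build GRCm38.p5; versions of the first pair are not given in the sources used here. The gene table holds 54232 genes, of which 99.72% had a symbol in the reference annotation, and the upstream tables hold 30166 regions each. Of the compared gene positions, 97.52% were identical to those of GENCODE M21, and 97.97% of regions end 1 base before their gene.

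Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, robust, genotype as the single term) after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors were 0.955 and 0.942 in WT replicates 1 and 2, and 1.04 and 1.07 in KO replicates 1 and 2. Upstream regions were tested with library sizes and factors of the gene table, so that a general shift is kept. The SE of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, over 27 lists with at least 5 tested genes. With the preset correlation 14 lists passed and with an estimated correlation 0. The exosome, macrophage and X-linked lists lost their call at estimated correlations of 0.0020, 0.0042 and -0.00092, below the preset. A correlation below the preset does not by itself weaken the test, so correlation among their genes did not cause these losses. Loss of a call in this version is therefore not a measure of gene correlation. Fry, a planned directional set test, passed the 14 lists except Sertoli cells (adjusted p = 0.0582) and adipose tissue (0.107). It also passed peritubular myoid cells (0.0261), blood cells (0.0458), p53 targets (0.0458), snoRNA host genes (0.0225) and cholesterol synthesis (0.0147). Upstream reads per 1000 gene reads were compared by exact permutation of the 4 libraries (6 relabellings, smallest two-sided p = 0.333).

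Background was estimated after the data were seen, as the mean reads of upstream regions of untested autosomal genes after dropping a fraction of 0.25 at each end (n = 13054). Reads per region on 1 strand were 8.67 and 8.17 in WT replicates 1 and 2, and 9.52 and 10.7 in KO replicates 1 and 2. This rate times gene length was subtracted from each count, with X and Y scaled to the level found on X. Nothing was subtracted from genes elsewhere, such as the mitochondrially encoded ones. Levels of upstream regions by expression of the gene are interquartile means over autosomal regions. Subtraction moved the log2 fold change of genes at 5 times background or more by a median of 0.12, because TMM then scaled the libraries anew, and by -0.02 in a further fit that kept the library scale of the counts as they were.

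Named genes follow a rule fixed before the data were examined: Dis3 and 5 further exosome genes with the smallest adjusted p; the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 1, non-overlapping groups and no predicted symbol; up to 4 genes of each list that passed or had a called member; and the 5 largest rises and 5 largest falls per upstream table with a mean of at least 10 reads. Gene lists and most of the settings tried below were fixed at the same time. Where another gene is named, it was chosen after its values were seen, as were Dynlt1a, Dmrt1, Neurog3, Ccnd2, Polr1a, Noc2l, Hist1h2ad, Bst2, Nsdhl, Fosl2, the small RNA genes other than Rnu11, Dynlt1c and Dynlt1f. Alternatives were DESeq2 1.42.0, median-of-ratios scaling, no filter, a filter of 1 CPM in 2 libraries, a replicate block, each library left out in turn, scaling to Sertoli cell genes, scaling of the upstream tables on themselves and regions clear of other genes. Background subtraction with either library scale, genes at 5 times background and antisense relative to sense were added after the data were seen.

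Replicates differed beyond sampling noise, with a chi-square per degree of freedom over genes of 4.54 in WT and 5.08 in KO. Each library was entered as 1 sample, and whether the animals were separate is not given in the sources used here. Correlations of log2 CPM were 0.988 within each group. The 10 most abundant genes took 4.72% to 5.99% of reads.

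The tests were tried on simulated counts drawn from the real means and library sizes, with 200 changed genes. Of genes changed by 1.5-fold, 2-fold and 4-fold, 33 of 67, 48 of 67 and 63 of 66 were recovered among 25076 genes, with 3 false calls among 147 calls. For upstream regions the same folds gave 0 recovered among 200 antisense regions, and 9 of 66 sense regions at 4-fold with 0 at smaller folds. Larger folds were therefore simulated afterwards. At 4-fold, 8-fold and 16-fold 24 of 67, 50 of 67 and 51 of 66 antisense regions were recovered with 6 false calls, and 25 of 67, 43 of 67 and 46 of 66 sense regions with 12 false calls among 126, or 9.52%, above the nominal threshold. Single upstream regions with isolated changes of 2-fold were thus not recovered at the depth, number of libraries and dispersion (0.08) simulated, which were not varied. A flat background of unequal share added to unchanged genes gave 52 false calls as counted and 0 after subtraction at its known rate, so the estimate of the rate was not put to this test. The simulated means came from the real counts, which already held background, spread there in proportion to library size. The number of false calls thus does not carry over to the data. The set test recovered a pachytene list lowered by 1.5-fold and called 0 other lists, the piRNA list that shares genes with it set aside. Simulated genes were drawn independently of each other, whereas the estimated correlation of the pachytene list in the data was 0.169. This simulation thus does not show how often the preset correlation gives false calls among correlated genes.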

Results

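RNA was measured by strand-specific RNA sequencing in whole testes of mice at postnatal day 17, an age at which the leading germ cells are in meiotic prophase. The 4 libraries comprised 2 from control mice (WT) and 2 from mice with a conditional knockout of Dis3 (KO). Dis3 encodes a ribonuclease of the RNA exosome, the complex that degrades and trims RNA from its 3′ end. The gene table held 31031920 and 40329170 reads for WT replicates 1 and 2, and 17663416 and 19255782 reads for KO replicates 1 and 2. A pair of further tables counted reads in the 3000 bases directly upstream of each gene, on the strand of the gene (sense) and on the opposite strand (antisense). Their totals ranged from 345584 to 421424 reads per library. Expression is given as CPM on the TMM-scaled library size, as mean ± SD with n = 2 per group, and log2 fold changes (KO over WT) are given ± SE. Nothing in the labels says that the libraries came from separate animals, so the edgeR p-values measure the spread between these libraries. Camera p-values at the preset correlation set the genes of a list against the other genes and do not measure that spread. Those with an estimated correlation were larger even for lists whose correlation lay below the preset, so they do not measure gene correlation alone. Reads in regions upstream of autosomal genes with too few reads to be tested, which were near equal on both strands, were used as a measure of background. This background corresponded to 1.07% and 0.772% of gene reads in WT replicates 1 and 2, and to 2.07% and 2.13% in KO replicates 1 and 2.

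The first comparison asked which genes differed between control and knockout testes, beginning with the targeted gene. Dis3 (ENSMUSG00000033166, GRCm38 chromosome 14, 99075206 to 99099770) fell from 80.5 ± 0.295 CPM in WT to 41.2 ± 2.35 CPM in KO, a log2 fold change of -0.96 ± 0.0729 (edgeR quasi-likelihood test, adjusted p = 2.34e-09). Reads were counted over the whole gene in whole testis, so that reads from outside the deleted part and from cells that keep the gene also count. Its relative Dis3l, the ribonuclease of the cytoplasmic exosome, fell by 0.84 ± 0.0633 on the log2 scale, and Skiv2l, a helicase that works with the cytoplasmic exosome, fell by 0.61 ± 0.0684. Of the 28 tested genes of the exosome and its cofactors, 15 fell, 0 rose and 13 did not pass the test (16 fell when adjusted over the list alone). The core subunit gene Exosc5 fell by 0.66 ± 0.0889 and Exosc10, a nuclear ribonuclease of the complex, by 0.40 ± 0.0621. Mpp6, which also fell (log2 fold change -0.51 ± 0.0664), encodes under this symbol a membrane palmitoylated scaffold protein and not the exosome cofactor of similar name; it is included in these counts and in the set test. The list was lower as a whole (median -0.25, camera adjusted p = 8.00e-06; adjusted p = 0.233 with an estimated correlation). After background was subtracted, its median was -0.27 with the library scale as counted (15 lower, 0 higher) and -0.13 after TMM scaling anew (11 lower, 1 higher). The camera adjusted p was then 0.000755 and 0.00498 in the same order. The lists of early meiotic and pachytene genes had lower medians, as given below.

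Across the 25076 genes tested, 2906 were higher and 5092 were lower in KO. Of the 16436 that held at least 5 times the background reads, 5081 were lower, and their median log2 fold change was -0.12. The other 8640 had a median of 0.73. Camera set each list against all tested genes, so a modest fall in a list of well expressed genes is to be read beside the first median. Among the genes that fell most was Ptprv, annotated as a processed transcript of a receptor phosphatase gene (chromosome 1, 135108497 to 135132594), which went from 67.7 ± 1.93 to 13.6 ± 0.407 CPM (log2 fold change -2.32 ± 0.0878, adjusted p = 3.43e-14 by edgeR). Nr4a1, an orphan nuclear receptor gene induced early after stimulation (chromosome 15, 101254269 to 101274795), went from 62.9 ± 0.799 to 15.8 ± 0.387 CPM (-1.99 ± 0.0861). Shcbp1l fell from 267 ± 18 to 94.6 ± 3.52 CPM (-1.50 ± 0.0648). The remaining genes named on this side were Pmis2 (-1.99 ± 0.33), Lkaaear1 (-1.77 ± 0.256), Mmel1 (-1.74 ± 0.226), Cpn1 (-1.62 ± 0.14) and Pdzd9 (-1.58 ± 0.124).

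Of the genes that rose, Frmd4b went from 24.6 ± 0.157 to 64.6 ± 0.286 CPM (log2 fold change 1.39 ± 0.078, adjusted p = 1.83e-11 by edgeR; chromosome 6, 97286867 to 97617541). Stc1, which encodes the hormone stanniocalcin, went from 10.6 ± 0.639 to 27.5 ± 3.50 CPM (1.38 ± 0.115), and Rnu11, the U11 RNA of the minor spliceosome, from 5.21 ± 0.721 to 15 ± 0.0923 CPM (1.51 ± 0.144). Hecw1 rose by 1.43 ± 0.282 as counted, from 50 and 42 reads in WT replicates 1 and 2 to 60 and 85 in KO. The gene is 14672 bases long. Background per kilobase and strand was 2.89 and 2.72 reads in WT replicates 1 and 2, and 3.17 and 3.56 in KO. Its WT reads thus lay close to background, and the size of its rise is uncertain. Epha5 (1.53 ± 0.366) and Otog (1.42 ± 0.297) rose as counted, and after background was subtracted their log2 fold changes were larger, at 2.46 and 2.01, with adjusted p of 0.125 and 0.183. These larger values rest on the floor of the subtraction. Epha5 in WT replicate 2 (26 reads) and Otog in WT replicate 1 (28 reads) lay below background and kept no reads. Fabp4, a fatty acid binding protein gene, rose by 2.01 ± 0.419 with 38 and 111 reads in KO replicates 1 and 2, and without KO replicate 2 its adjusted p was 0.0818. Dynlt1b had 3 reads in both WT libraries together and 655 in the KO libraries, a ratio of 380 (95% Clopper-Pearson interval 129 to 1845, counting error only). It is uncertain because it belongs to a family of near-identical neighbouring copies and reads that map to several places were left out. The mice are B6D2F1 crosses per the labels, and a strain difference at these genes was not tested. Its neighbour Dynlt1a fell by 0.86 ± 0.132. The count of higher genes was sensitive to low-count genes: 1523 of the 2906 held fewer than 5 times the background reads. So did 1308 of the 1442 that rose by 2-fold or more, and 8640 of all 25076 tested. The count of 2906 also changed with the setting. It was 1008 with DESeq2, and 1537, 1521 and 1324 without WT replicate 2, KO replicate 1 and KO replicate 2. Scaling to Sertoli cell genes gave 2146 higher and 6455 lower.

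Genes of meiotic germ cells fell, with the lowest median among the germ cell lists in pachytene spermatocytes, the cells of mid-meiotic prophase. Of 34 tested pachytene markers, 30 fell, 0 rose and 4 did not pass the test (median -0.66, camera adjusted p = 1.33e-22; adjusted p = 0.233 with an estimated correlation). Ldhc, the germ cell lactate dehydrogenase, fell from 566 ± 4.82 to 311 ± 28.4 CPM (-0.86 ± 0.065), Adam2, a sperm surface protein gene, from 158 ± 0.740 to 78.8 ± 4.68 CPM (-1.0 ± 0.0643), Spink2 by 0.94 ± 0.0609 and Zmynd10 by 0.93 ± 0.0645. Of 38 early meiotic prophase genes, 34 fell and 0 rose (median -0.48, camera adjusted p = 1.36e-17; adjusted p = 0.233 with an estimated correlation). They included the synaptonemal complex genes Syce3 (-0.88 ± 0.0646) and Syce1 (-0.79 ± 0.0637), the meiotic cohesin gene Stag3 (-0.76 ± 0.0663) and Meioc (-0.58 ± 0.0591), which acts at meiotic entry. Counts adjusted over the list alone were also 30 and 34.

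Of 17 markers of differentiating spermatogonia, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.31, camera adjusted p = 1.21e-06; adjusted p = 0.246 with an estimated correlation). Dmrtb1, a regulator of the switch from mitosis to meiosis, fell by 0.81 ± 0.0803, Tuba3b by 0.71 ± 0.0644, Prss50 by 0.55 ± 0.0694 and Uchl1 by 0.41 ± 0.0618, while the cyclin gene Ccnd2 rose (0.28 ± 0.0674). With background subtracted, 13 were lower with the library scale as counted and 8 after TMM scaling anew (median -0.18). Of 22 markers of undifferentiated spermatogonia, 3 rose and 2 fell, and the list did not pass (camera adjusted p = 0.544). Id4, a stem cell factor, fell by 0.56 ± 0.0619 and Lin28a by 0.38 ± 0.105, while Tspan8 (1.40 ± 0.355) and Lhx1 (1.05 ± 0.31) rose at mean levels of 2.14 and 2.54 CPM in KO, as did Neurog3 (0.74 ± 0.239). Of 17 tested spermatid genes, 7 fell and 0 rose (median -0.07, camera adjusted p = 0.0241; adjusted p = 0.279 with an estimated correlation), among them the acrosomal genes Acr (-0.88 ± 0.0736) and Zpbp (-0.90 ± 0.0807), with Gk2 (-0.97 ± 0.0748) and Odf2 (-0.62 ± 0.0626). After background was subtracted 13 genes of this list were tested, with a median of -0.60 with the library scale as counted and -0.46 after TMM scaling anew. With the leading germ cells in meiotic prophase at this age, the list is not a measure of spermatids.

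**Figure D1:**
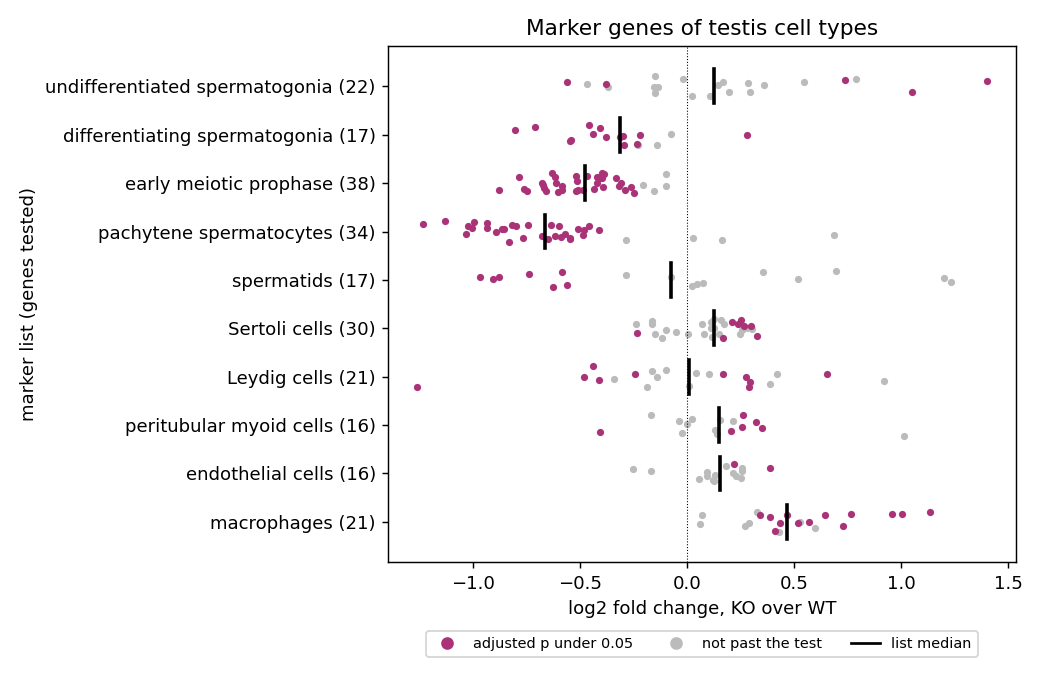
Each point is the log2 fold change, KO over WT (x axis), of 1 marker gene, in rows by marker list with the number of genes tested, and vertical bars mark list medians. Coloured points have an edgeR adjusted p under 0.05, and the medians of the 10 lists shown run from -0.66 in pachytene spermatocytes to 0.47 in macrophages.

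Markers of macrophages rose. Of 21 tested, 13 rose, 0 fell and 8 did not pass the test (14 rose adjusted over the list alone; median 0.47, camera adjusted p = 1.48e-07; adjusted p = 0.233 with an estimated correlation). The lysosomal protein gene Cd68 went from 20.4 ± 0.356 to 45 ± 6.43 CPM (1.13 ± 0.0967) and the lysozyme gene Lyz2 from 16.1 ± 1.34 to 31.4 ± 0.714 CPM (0.96 ± 0.0991). The complement gene C1qc rose by 1.0 ± 0.121 and Laptm5 by 0.77 ± 0.107. Of 30 markers of Sertoli cells, the supporting cells of the seminiferous tubule, 7 rose and 1 fell, the same numbers adjusted over the list alone (median 0.13, camera adjusted p = 0.0241; adjusted p = 0.409 with an estimated correlation). Kitl, which encodes a germ cell growth factor, rose by 0.33 ± 0.062, Vim by 0.27 ± 0.0593 and the sex-determining factor gene Sox9 by 0.25 ± 0.0602. The member that fell was Dmrt1 (-0.24 ± 0.0606), which spermatogonia also express. The Sertoli call was lost without WT replicate 1 (adjusted p = 0.210), without KO replicate 2 (0.0861) and with median-of-ratios scaling (0.0584). After background was subtracted, 6 of the 30 were higher and 1 was lower with the library scale as counted, and 16 and 0 after TMM scaling anew, which moved well expressed genes up by a median of 0.12.

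**Figure D2:**
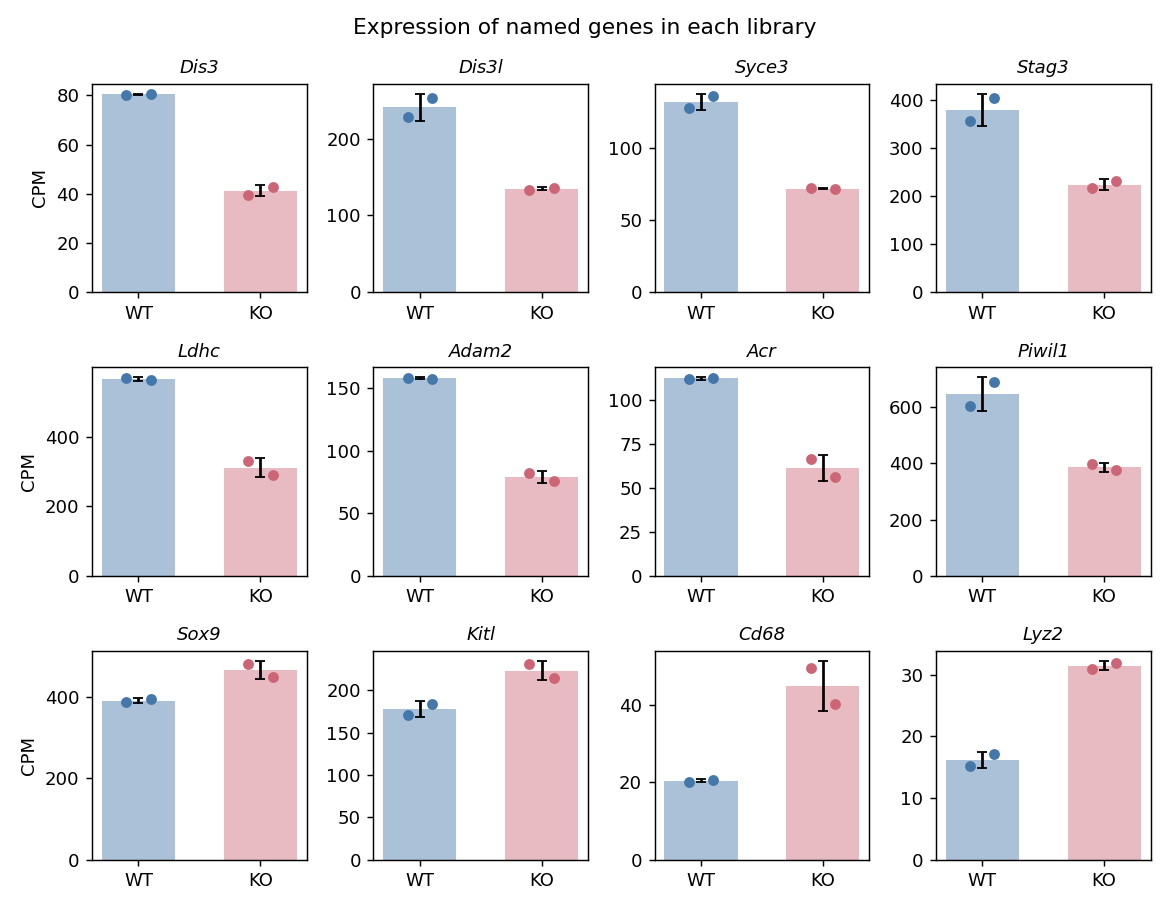
Bars give the mean CPM (y axis, from 0) of 12 named genes in WT and KO, error bars the SD and points the 2 libraries of each group. Dis3 lies at 80.5 CPM in WT and 41.2 in KO, and Cd68 at 20.4 and 45.

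Steroid-producing Leydig cells showed changes both ways: of 21 markers 5 rose and 5 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.996). Hsd3b6, a steroid dehydrogenase of adult Leydig cells, rose by 0.65 ± 0.0594, whereas Hsd3b1 fell by 0.41 ± 0.0723, the cholesterol carrier gene Star by 0.48 ± 0.0657 and Ptgds by 1.26 ± 0.215. Of 16 peritubular myoid markers 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0570). Nr2f2 (0.35 ± 0.0675), Ptch1 (0.32 ± 0.0628) and Smoc2 (0.26 ± 0.0754) rose, and the smooth muscle actin gene Actg2 fell (-0.41 ± 0.112). Of 16 endothelial markers 2 rose and 0 fell, both counts also adjusted over the list alone (camera adjusted p = 0.104): Kdr (0.39 ± 0.103) and Cdh5 (0.22 ± 0.0678). Of 5 blood cell genes 3 fell, also adjusted over the list alone (camera adjusted p = 0.243): the globin genes Hbb-bt (-1.42 ± 0.22) and Hbb-bs (-2.32 ± 0.51), and Alas2 (-0.98 ± 0.239). Of 8 adipose genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.010; adjusted p = 0.407 with an estimated correlation): Plin1 (0.83 ± 0.12), Lpl (0.98 ± 0.147) and Fabp4. Without KO replicate 2 the adipose call was lost (adjusted p = 0.0861). Of 6 epididymal genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.243), Gpx5 and Ovch2, at 0.538 and 0.876 CPM in KO. After background was subtracted, Ovch2 had a larger log2 fold change of 2.16 with an adjusted p of 0.115, and Gpx5 had too few reads to be tested.

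Genes of the piRNA pathway, which silences transposons in germ cells, fell together: of 29 tested 23 fell and 0 rose, also adjusted over the list alone (median -0.49, camera adjusted p = 1.22e-14; adjusted p = 0.233 with an estimated correlation). Piwil1 (-0.74 ± 0.0666), Ddx25 (-0.73 ± 0.0664), Tdrd1 (-0.66 ± 0.0618) and Mael (-0.64 ± 0.06) are examples. Piwil1, Mybl1 and Tdrd5 are on both this list and that of pachytene markers. Of 23 sex chromosome silencing factors, 14 fell and 0 rose (16 adjusted over the list alone; median -0.32, camera adjusted p = 9.54e-07; adjusted p = 0.233 with an estimated correlation). They included the checkpoint kinase gene Atr (-0.47 ± 0.059), Mdc1 (-0.51 ± 0.0633), Bard1 (-0.52 ± 0.0752) and Fanca (-0.91 ± 0.123). With background subtracted, 15 factors were lower with the library scale as counted (median -0.34) and 12 after TMM scaling anew (median -0.20). Of 802 X-linked genes 98 rose and 38 fell (64 and 30 adjusted over the list alone; median 0.11, camera adjusted p = 0.00672; adjusted p = 0.233 with an estimated correlation). Over all 25076 tested genes 2906 rose and 5092 fell, so X-linked genes rose about as often and fell less often. After background was subtracted, 71 X-linked genes were higher and 39 lower with the library scale as counted (median 0.06), and 170 and 18 after TMM scaling anew (median 0.20). Cd99l2 (0.75 ± 0.0836), Vegfd (0.73 ± 0.0913) and Nrk (0.49 ± 0.07) rose and Gm6472 fell (-1.33 ± 0.0703). Of 16 Y-linked genes 3 rose, Gm20788, Gm3376 and Gm20834, members of multicopy families with uncertain counts, and 1, Uba1y (-0.26 ± 0.069), fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.337).

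Of 42 ribosome biogenesis genes, 24 fell and 2 rose (25 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 9.54e-07; adjusted p = 0.233 with an estimated correlation), with Rrp1 (-0.47 ± 0.0597), Ddx10 (-0.39 ± 0.0592), Wdr12 (-0.51 ± 0.077) and Noc3l (-0.42 ± 0.07). Polr1a (0.25 ± 0.0624) and Noc2l (0.24 ± 0.0672) rose. With background subtracted, 24 were lower and 2 higher with the library scale as counted, and 16 and 4 after TMM scaling anew (median -0.09). The camera adjusted p was then 0.000476 and 0.0310 in the same order. Of 61 replication-dependent histone genes 22 fell and 1 rose (23 and 1 adjusted over the list alone; median -0.16, camera adjusted p = 0.00530; adjusted p = 0.279 with an estimated correlation), with Hist1h4n (-0.55 ± 0.0722) and Hist1h2ak (-0.45 ± 0.0613) among those that fell. Hist1h2ad rose (1.13 ± 0.272). The histone call was lost with the stricter filter (adjusted p = 0.0507) and after background was subtracted, both with the library scale as counted (0.183, median -0.22, 22 lower) and after TMM scaling anew (0.148, median -0.09, 14 lower). Histone genes are near-identical copies, so their single counts are uncertain. Of 30 interferon-stimulated genes 8 rose and 1 fell, also adjusted over the list alone (median 0.22, camera adjusted p = 0.00772; adjusted p = 0.236 with an estimated correlation). Ddx58 (0.49 ± 0.116), Ifitm3 (0.25 ± 0.0721), Oas2 (1.19 ± 0.323) and Ifit2 (0.95 ± 0.26) rose and Bst2 (-0.28 ± 0.105) fell. With background subtracted, 5 of this list were higher and 0 lower with the library scale as counted (median 0.15), and 12 and 0 after TMM scaling anew (median 0.29).

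The remaining lists did not pass camera. Among them fry passed the lists of p53 targets, cholesterol synthesis and snoRNA host genes. Of 30 p53 target and apoptosis genes 4 rose and 3 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.480): Bcl2l11 rose by 0.52 ± 0.103 and Mdm2 fell by 0.29 ± 0.0642. Of 25 genes of the integrated stress response 6 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.535), with the cystine transporter gene Slc7a11 at 0.74 ± 0.149 and Ddit3 at -0.42 ± 0.102. Of 21 immediate early genes 3 rose, Egr2 (0.74 ± 0.175), Myc (0.37 ± 0.113) and Zfp36 (0.25 ± 0.083), and 2 fell, Nr4a1 and Fosl2 (-0.26 ± 0.0919), also adjusted over the list alone (camera adjusted p = 0.544). Of 24 cholesterol synthesis genes 2 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.0530), with Nsdhl (0.44 ± 0.0974) rising, and Fdft1 at -0.50 ± 0.0762 and Idi1 at -0.69 ± 0.134. Of 16 snoRNA host genes 1, Snhg14 (0.75 ± 0.255), rose and 2, Snhg5 (-0.37 ± 0.125) and Snhg15 (-0.41 ± 0.152), fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.996). Of 27 mitochondrially encoded genes 0 rose and 0 fell by edgeR, also adjusted over the list alone (camera adjusted p = 0.130). No background was subtracted from these genes, so their result after subtraction rests on the other genes and the scale. Their median was 0.08 as counted. With the other genes subtracted it was 0.08 with the library scale as counted and 0.22 after TMM scaling anew. The list passed as higher without KO replicate 2 (adjusted p = 8.36e-12), without WT replicate 1 (0.0174), with the stricter filter (0.0174), with a replicate block (0.0176) and after background was subtracted (0.00166). It did not pass without WT replicate 2 (adjusted p = 0.317). Without KO replicate 1 its direction was lower, and it did not pass (0.449).

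The second comparison asked whether RNA from regions upstream of promoters, a known exosome substrate, differed between the groups. Upstream of genes with over 1000 reads (n = 3285 regions), background-subtracted antisense reads (interquartile mean) were 0.316 ± 0.00163 CPM per region in WT and 0.572 ± 0.0251 in KO (mean ± SD, n = 2), a ratio of 1.81. Ratios of single KO to single WT libraries ran from 1.75 to 1.87. On the sense strand of the same regions the levels were 0.165 ± 0.000161 and 0.159 ± 0.0163, a ratio of 0.967. Antisense minus sense reads, which need no background estimate, were 0.151 ± 0.00179 in WT and 0.413 ± 0.0414 in KO. For genes with over 100 to 1000 reads (n = 3421) the antisense ratio was 1.68 and the sense ratio 1.23.

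**Figure D3:**
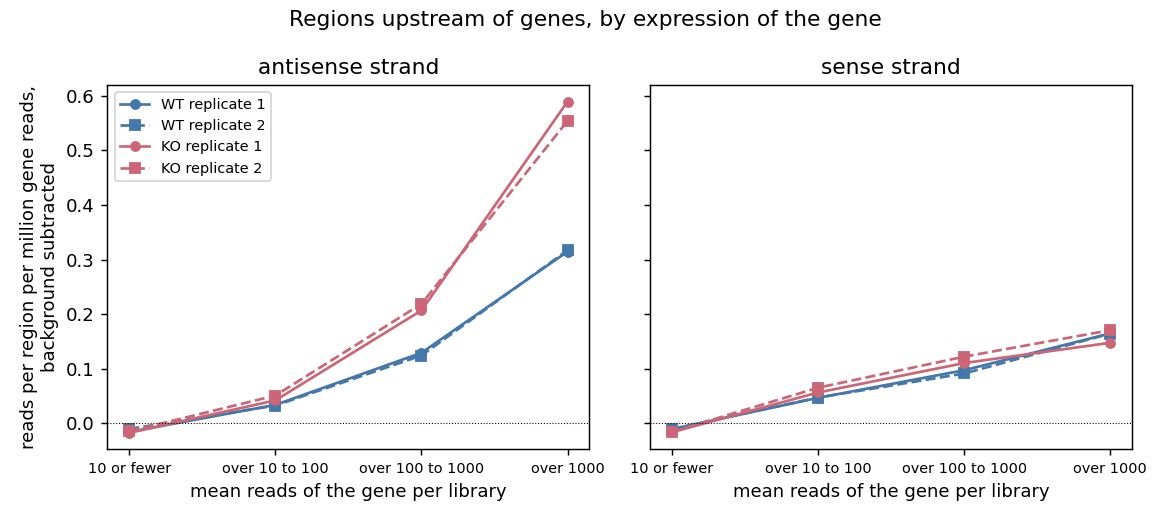
Background-subtracted CPM per upstream region (y axis) in each of the 4 libraries, by the mean reads of the downstream gene (x axis, 4 classes), antisense on the left and sense on the right. For genes over 1000 reads the KO libraries lie at 0.589 and 0.554 on the antisense strand and the WT libraries at 0.315 and 0.317, while on the sense strand all 4 lie between 0.148 and 0.171.

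Before subtraction, upstream reads relative to gene reads were higher in KO on both strands. The upstream reads themselves were not. Antisense totals were 384084 and 412142 in WT and 384808 and 413505 in KO, and sense totals 390752 and 421424 in WT and 345584 and 383137 in KO. Both KO libraries held fewer gene reads than both WT libraries, so depth and genotype cannot be told apart in these ratios. Antisense reads per 1000 gene reads were 12.4 and 10.2 in WT and 21.8 and 21.5 in KO, and sense reads 12.6 and 10.4 in WT and 19.6 and 19.9 in KO. Both comparisons gave p = 0.333 in an exact two-sided permutation test, the smallest p that 4 libraries allow. Regions upstream of 13054 autosomal genes with too few reads to be tested held 2.05 times the CPM of WT in KO, at 2.08 on the antisense and 2.07 on the sense strand. Of 18596 antisense regions tested, 2143 were higher and 21 lower (median log2 fold change 1.01). Of 18393 sense regions 10 were higher and 1 was lower (median 0.93), with 5715 and 91 at an unadjusted p under 0.05 by edgeR. The count of 10 was 2618, 272, 26 and 12 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2, and 1094 without a filter, so the counts of the strands are not a measure of their difference.

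The antisense region of Flad1 (chromosome 3, 89411871 to 89414870), a flavin nucleotide synthase gene, rose by 4.34 ± 0.693 on the log2 scale, from 3 and 1 reads in WT to 21 and 30 in KO, while the gene itself fell by 0.60. That of Rlim, a ubiquitin ligase gene (chromosome X, 103981285 to 103984284), rose by 3.77 ± 0.567. Those of Gm48525 (4.04 ± 0.684), Gm10440 (3.73 ± 0.685) and Gm13678 (3.72 ± 0.685) also rose. Antisense regions that fell included those of Rgcc (-1.22 ± 0.32), Tm9sf3 (-0.86 ± 0.172), Gm5922 (-1.28 ± 0.246), 4930520O04Rik (-0.97 ± 0.16) and 2310022B05Rik (-0.96 ± 0.295). On the sense strand, the regions of Gm11523 (3.72 ± 0.373), Mrpl35 (3.07 ± 0.417), Uimc1 (2.39 ± 0.299), AC134830.1 (1.74 ± 0.276) and Gm10801 (1.67 ± 0.272) rose, and that of 4921513H07Rik fell (-0.92 ± 0.14) together with its gene (-1.04). The count of 2143 was 371 after background was subtracted and 48 when the upstream table set its own scale, and 4295, 1381, 355 and 442 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2. Tested against sense reads of the same region, 19 antisense regions were higher and 0 lower. None of the antisense regions named here were among them (adjusted p from 0.110 for Flad1 to 0.769 for Gm48525).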

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

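Background subtraction, the limit to genes at 5 times the background and the antisense to sense test were chosen after the data were seen; the other alternatives were planned. The fall of Dis3 kept its direction and its call in all settings where it was read out, from -0.86 to -1.08 on the log2 scale, the latter without KO replicate 2. It was not read out in the fit limited to genes at 5 times the background. Genes higher in KO (2906) numbered 1182 after background subtraction with the library scale as counted and 2512 with TMM scaling anew, 1008 with DESeq2, 1937 without a filter, 1523 in a new fit of only the genes at 5 times the background or more, and 1324 to 2429 with 1 library left out. Genes lower in KO (5092) numbered 5406 after background subtraction with the library scale as counted and 3337 with TMM scaling anew, and 4060 to 5260 with 1 library left out. Antisense regions higher (2143) numbered 773 with DESeq2, 1384 with the stricter filter, 48 when scaled within the upstream table, 371 after background subtraction, 19 relative to sense, and 355 to 4295 with 1 library left out. Antisense regions lower (21) numbered 59 with the stricter filter, 139 when scaled within the table, 0 relative to sense and 8 to 34 with 1 library left out. The antisense median (1.01) was 0.88 with the stricter filter, 0.0011 when scaled within the table, 0.77 after background subtraction and 0.88 to 1.23 with 1 library left out. Sense regions higher (10) numbered 1094 without a filter, 186 with the stricter filter, 2 when scaled within the table, 2 after background subtraction and 12 to 2618 with 1 library left out. Sense regions lower (1) numbered 7 with DESeq2, 31 without a filter, 39 with the stricter filter, 57 when scaled within the table, 0 after background subtraction and 5 to 31 with 1 library left out. The sense median (0.93) was 0.24 with the stricter filter, reversed to -0.0107 when scaled within the table, and was 0.0707 after background subtraction and 0.81 to 1.16 with 1 library left out. Scaling within the upstream table removes a shift common to its regions by construction; for the other settings the cause was not tested. Where 1 library was left out, the lone library was assumed to vary like the other group. Of the 27 lists, 14 passed in the main test, 13 to 17 in the other settings with all libraries at the preset correlation and 0 with an estimated correlation. Which lists passed changed when WT replicate 1 or KO replicate 2 was left out, with Sertoli cells lost in both cases. With the stricter filter 25 lists, and after background subtraction 26, had enough tested genes. Lists that passed after subtraction and not before were peritubular myoid cells (adjusted p = 0.000194), endothelial cells (0.0310), p53 targets (0.0310) and mitochondrial genes, and cholesterol synthesis passed without KO replicate 2 (0.0371). With the library scale as counted the p53 list did not pass (0.0899) and the Y-linked list did (0.0333). The replicate numbers do not pair the libraries by any label, and the deviations of same-numbered libraries correlated at -0.0083 over genes. With a replicate block 3362 genes were higher and 5469 lower, 3210 antisense regions were higher and 32 lower, and 1655 sense regions were higher and 42 lower, with 15 lists past the test. Among named genes and regions other than Dis3 no direction reversed in the settings where each could be tested. They were not read out when scaled to Sertoli genes or limited to 5 times the background or to regions clear of other genes. With DESeq2 117 of 131 named results kept their status, and with background subtraction 111 of 131, with 19 no longer past the threshold. These numbers include named genes that did not pass in the main test and still did not. The median upstream region held 8 to 11 reads per library.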

Other observations

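Of 9 small nuclear RNA genes tested, 6 were higher and 0 lower after background subtraction (median log2 fold change 1.95), and Gm22753, Gm24666 and Gm23205 did not pass. The group was chosen after its values were seen and no set test was run on it. Rnu11, the U11 RNA of the minor spliceosome, rose by 1.65 ± 0.15 after subtraction. Gm22513 and Gm24305, a pair of 164-base snRNA genes on chromosome 12, had 5 and 8, and 0 and 4, reads in WT replicates 1 and 2, against 166 and 230, and 84 and 119, in KO replicates 1 and 2. The labels name polyA RNA and a protocol with random priming, and a B6D2F1 cross, so that neither the input of small RNA nor a strain difference at these genes was settled here. Of 29 small nucleolar RNA genes tested, 5 were higher and 1 was lower (median 0.58). Rnu3b2, a copy of the U3 RNA of ribosomal RNA processing, rose by 2.84 ± 0.42 and Snora21 by 2.08 ± 0.52, whereas Gm24339 fell by 0.36 ± 0.12. Of 7 scaRNA genes 0 passed by edgeR. The median of lincRNA genes was 0.49 as counted and -0.02 over 865 genes after subtraction, and that of genes from bidirectional promoters 0.34 as counted and 0.24 over 112 genes after subtraction. Many of these RNAs have near-identical copies, and reads mapping to several of them were left out, so values of single genes are uncertain.

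The Dynlt1 neighbours on chromosome 17 did not share the direction of Dynlt1b, which had 2 and 1 reads in WT and 350 and 305 in KO. Dynlt1a fell (-0.86 ± 0.132), while Dynlt1c (-1.26 ± 0.784, adjusted p = 0.363) and Dynlt1f (-0.22 ± 0.178, adjusted p = 0.362) did not pass.

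In the tests that follow, those of strand in quiet regions, of background alone for antisense reads, of higher calls at the library scale as counted, of macrophage against Sertoli markers and of pachytene against early meiotic markers were written after the result was seen.

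Upstream regions of genes with too few reads to be tested held more reads in CPM in KO. Accumulation of antisense transcripts there is argued against by strand symmetry: the KO over WT ratio of the antisense strand was 1.01 times that of the sense strand. A uniform background such as genomic DNA is a possible source. X-linked regions, present in 1 copy in males, held 0.429 and 0.437 of the autosomal level in WT replicates 1 and 2. They held 0.480 and 0.461 in KO replicates 1 and 2. Bootstrap 95% intervals over regions were 0.410 to 0.449, 0.414 to 0.457, 0.460 to 0.501 and 0.443 to 0.480 in the same order. Transcription from a single X could also give a lower level, so the ratio does not separate DNA from RNA. Upstream of genes over 1000 reads, background alone is argued against by a smallest KO to WT ratio of 1.75 after subtraction, and a change in the gene by a smallest ratio of 1.71 where the gene changed by less than 0.2. A higher level of antisense upstream RNA with loss of Dis3 stays open as a hypothesis, as do other differences between these 4 libraries, such as RNA quality, for which no test was run.

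Of the genes higher by 2-fold or more, 90.7% held fewer than 5 times the background reads, against 34.5% of all tested genes. Background adding reads to genes with few transcripts would give this pattern. A simulated flat background gave 52 false calls as counted. It was added to means that already held the real background, spread in proportion to library size. That count therefore does not bound how many of these calls come from background, and whether it accounts for all of them was not shown. For the 1383 higher genes at 5 times the background or more, background stays open as a cause. Of these 75.3% stayed higher after subtraction with the library scale as counted, short of the 80 percent set as the bound against it. Of the 5081 lower genes 99.5% stayed lower. With TMM scaling anew the shares were 96.8% and 64.6%, so both depend on the scale.

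Pachytene markers fell more than early meiotic markers after subtraction, with a difference of medians of -0.22 (33 and 38 genes, permutation test p = 0.00055, 100000 resamples, genes are not independent replicates). The median of 13 spermatid genes after subtraction, -0.46 (-0.07 over 17 genes as counted), lay above that of pachytene markers, -0.57. The leading germ cells at this age are in meiotic prophase, so these genes do not measure a later stage and cannot decide the question. A loss that grows with the stage of meiosis stays open. Macrophage markers lay 0.33 above Sertoli markers in the median, with the lower quartile of the first (0.43) above the upper quartile of the second (0.37). If neither list were expressed in spermatocytes, a lower share of these cells alone would raise both alike. Under that premise, which was not checked, the gap argues against a lower share as the whole cause. A change within cells, a changed number of macrophages and a delay of the first wave of meiosis stay open and were not tested.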
